A study of Mus musculus with 4 samples.

How the data were processed

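RNA of 4 mouse cultures was hybridised to Affymetrix mouse whole-genome expression arrays, with 15 µg of biotin-labelled cRNA made from 5 µg of total RNA, per the labels' protocols. The groups were taken from the labels, with 4FTSC (1 array), TSC-iPSC (2 arrays, clones 1 and 2 of line 2) and ESC (1 array), all of the strain background C57BL/6 x 129sv. The labels do not say that the clones were cultured or processed separately beyond being different clones, so p-values measure only the spread between these 2 samples.

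The values used were the authors' deposited intensity values per probe set, on a linear scale, made with RMA (background correction, quantile normalisation and probe summarisation) per the submitters' processing notes. The software and its version are not given in the sources used here. Each array was read as deposited, and log2 was taken without a pseudocount. No detection call was used, so a fold against a dim signal depends on the background correction, and dim values on the log2 scale, under about 5.31 (the median of all probe sets), set no absolute level of expression. The medians of the 4 arrays lay between 38.6 and 40.2.

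Probe sets were named from the GEO platform annotation, with 34958 of 45101 carrying 1 gene symbol, 932 several and 9211 none. Of the 34958, 34754 were matched through the gene identifier to the RefSeq table of assembly GRCm38.p6, and no symbol changed. The 64 control probe sets were left out of probe-set-level tests. A gene with several probe sets (9012 of 18194 genes) was represented by the probe set with the highest mean over the arrays; 5 genes had probe sets at least 2-fold apart in opposite directions between TSC-iPSC and 4FTSC. No genome build came with the values, so no coordinates are given. List members with no probe set of a single symbol were not analysed here, among them H19, Prl3d1, Ddx3y, Zscan4c, Zic3, T and Trp53.

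Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on 3 groups, with 1 residual degree of freedom from the 2 clones. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a mean log2 difference of at least 1. 4FTSC against ESC was compared by a size rule of 2-fold and not tested, as fixed before the data were examined, and so was clone 1 against clone 2, whose difference is the only estimate of spread. Named genes followed a rule set before the data were examined, as were the 20 gene lists, the tests and most alternatives: the 12 called genes with the largest rise and the 12 with the largest fall that were at least 2-fold apart in each clone, the 8 highest and 8 lowest genes where no test was made, and any list member. The lists held 317 different genes, of which 291 were measured. Their members were counted when called over all genes and when adjusted over the list alone, and each median was set against 10000 random lists of the same size in 20 bins of mean expression. A further 3 lists (trunk Hox genes, further fibroblast genes and markers of other tissues) were written after the first lists were seen. The position of TSC-iPSC was (TSC-iPSC minus 4FTSC) over (ESC minus 4FTSC) per gene. Correlation under a shared 4FTSC array was simulated 100 times with unchanged groups. Summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

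The limma step was tested on simulated data with 200 changed genes and, on every array, noise resampled from the differences between the clones. For TSC-iPSC against 4FTSC with the tied genes kept (18194 genes), it recovered 0% of the changes at log2 sizes of 1.5, 3, 4.5 and 6. With genes tied in the simulated arrays left out (16092 genes), it recovered 91.3% at 1.5 and 100% at 3, 4.5 and 6, with 4 false calls. Far more genes differed in the measured data, with 2438 at least 2-fold apart in both clones, and the same fit called 1321. The 0% therefore does not give the recovery there. The lone arrays may vary more than the clones, so the 4 false calls do not measure the error there. On the measured data the prior degrees of freedom were 0.61 with tied genes and 6.64 without them. The fit with tied genes was kept as the main result, as fixed before the data were examined, and the fit without them, chosen after seeing the data, is given beside it.

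Alternatives were the mean or the most variable probe set of a gene, a filter on dim genes, quantile normalisation, median centring, eBayes with a trend or robust, other size limits, limma treat, probe sets in place of genes, a 2-group fit of 4FTSC against the other 3 arrays, leaving out arrays, another correlation or gene set, and, chosen after seeing the data, leaving out tied genes, leaving out genes at least 0.5 (log2) above ESC, and 1 variance for all genes.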

Results

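Gene expression was measured on 4 Affymetrix mouse whole-genome arrays. The first was of 4FTSC, trophoblast stem cells derived from mouse blastocysts collected at 3.5 days post coitum that carried doxycycline-inducible Oct4, Sox2, Klf4 and cMyc. Trophoblast stem cells are the self-renewing precursors of the placenta. A pair of arrays was of TSC-iPSC clone 1 and clone 2, which were picked as Oct4-GFP-positive colonies after 28 days of conversion of a 4FTSC line and then kept without doxycycline. The last was of mouse embryonic stem cells (ESC). The TSC-iPSC and ESC cells were grown in ESC medium with Lif, and the labels state that the TSC-iPSC colonies were plated on mouse embryonic fibroblasts, whereas 4FTSC were grown without feeder cells in 30% feeder-conditioned medium with FGF4 and heparin. The 4FTSC and ESC groups had n = 1 array and the TSC-iPSC group n = 2, so that any error given comes from the spread between the 2 clones, and this small number limits the precision. Median deposited intensities over 45101 probe sets were 38.6 for 4FTSC, 40.0 and 39.6 for the clones and 40.2 for ESC. After joining probe sets, 18194 genes were compared on the log2 scale. The question named in the series design was whether the extraembryonic mRNA profile of the parental cells had been left in TSC-iPSC.

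The 4 inducible factors were examined first, as a check of the labels. Pou5f1, which encodes Oct4, read 3.63 on the log2 scale in 4FTSC, 11.68 ± 0.02 (SD, n = 2) in TSC-iPSC and 11.60 in ESC. Klf4 read 7.33 in 4FTSC, 11.48 ± 0.16 (SD, n = 2) in TSC-iPSC and 10.99 in ESC. Sox2 was already bright in 4FTSC, at 10.59, against 11.41 ± 0.12 (SD, n = 2) in TSC-iPSC and 11.71 in ESC. Myc read 9.21 in 4FTSC, 8.68 ± 0.06 (SD, n = 2) in TSC-iPSC and 8.29 in ESC. In limma, Pou5f1 (adjusted p = 0.0404) and Klf4 (adjusted p = 0.0444) passed the threshold against 4FTSC, and Sox2 (adjusted p = 0.0958) and Myc (adjusted p = 0.0816) did not. The log2 differences of Sox2 (0.82) and Myc (-0.53) were also under the size limit of 1. Whether the probe sets of the 4 factors also see transgene mRNA is not given in the sources used here.

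Sex-linked transcripts did not match between the library labelled 4FTSC and those labelled TSC-iPSC, although the clones are labelled as clones of line 2 and the 4FTSC array as line 2. Xist, the RNA that coats the inactive X chromosome, read 10.60 in the library labelled 4FTSC, 7.83 and 7.86 in the clones and 7.57 in the ESC library. Its other probe sets read 9.48, 6.26, 4.95 and 4.53, and 7.05, 4.04, 3.58 and 3.35, in the same order. The Y-linked gene Eif2s3y read 2.97 in the library labelled 4FTSC, 7.35 and 7.97 in clones 1 and 2, and 8.61 in the ESC library. Uty, also Y-linked, read 3.71, 5.89, 5.74 and 5.78 in the same order. Of the other measured Y-linked genes, Kdm5d and Usp9y lay between 3.91 and 4.30 on every array. A second probe set of Uty read 2.01 in the library labelled 4FTSC, 6.09 and 6.26 in the clones and 6.47 in the ESC library, and another of Kdm5d read 1.93, 4.12, 4.36 and 3.11. The comparisons with 4FTSC below take the labels as given.

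Between TSC-iPSC and 4FTSC, pluripotency genes were far higher in TSC-iPSC and trophoblast stem cell genes far lower, together with a large excess of fibroblast genes in TSC-iPSC. Both clones were at least 2-fold above 4FTSC for 1558 genes and at least 2-fold below it for 880 genes. At least 8-fold in both clones, the counts were 354 higher and 88 lower. Limma called 1321 genes, of which 878 rose and 443 fell in TSC-iPSC. Of the 1558 higher genes, 767 also lay at least 0.5 (log2) above ESC in TSC-iPSC, as most fibroblast genes did. Without genes in that position, a count chosen after seeing the data, limma called 798 genes, of which 424 rose and 374 fell.

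Pluripotency factors had a median log2 difference of 2.60 over 26 measured genes, above all 10000 random lists of matched mean expression. Of these, 12 rose, 19 when adjusted over the list alone, and none fell; 19 were at least 2-fold higher in both clones. Nanog, a core factor of the ESC network, rose 125-fold (log2 difference 6.96 ± 0.11, SE, adjusted p = 0.0404). Tdgf1, a Nodal co-receptor, rose 256-fold, Fgf4 80.8-fold and Klf2 36.5-fold. Other members were already bright in 4FTSC: Esrrb read 9.75 there against 10.23 and 10.47 in the clones, Dppa4 10.61 against 9.96 and 10.10, Sall4 10.17 against 10.87 and 11.10, and Utf1 10.55 against 10.32 and 10.53.

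Trophoblast stem cell factors had a median log2 difference of -3.33 over 30 measured genes, below all 10000 random lists. Of these, 18 fell, 27 when adjusted over the list alone, and none rose; 27 were at least 2-fold lower in both clones. Elf5, a transcription factor of the trophoblast stem cell state, showed the largest decrease of any called gene, from 11.67 in 4FTSC to 4.56 ± 0.02 (SD, n = 2) in TSC-iPSC, or 138-fold; the TSC-iPSC value lay under the dim limit of 5.31, so that the fold and its rank depend on the background correction. Cdx2 and Eomes, which specify trophectoderm, were 30.5-fold and 36.1-fold lower (adjusted p = 0.0404 and 0.0411). Gata3 fell 24.0-fold, the FGF4 receptor gene Fgfr2 13.6-fold and the surface marker Plet1 18.6-fold. The simple-epithelium keratins Krt8 and Krt18 fell 20.8-fold and 27.6-fold. Bcam was the exception, at 7.47 in 4FTSC and 7.50 and 7.86 in the clones. Markers of differentiated trophoblast had a median of -0.97 over 21 genes, of which 6 fell, 8 when adjusted over the list alone, and none rose. The prolactin family gene Prl7a1 and the placental cathepsin Ctsj were among them, 39.1-fold and 15.4-fold lower. Several markers of mature placental cells were dim on all 4 arrays, such as Tpbpa at 3.49 to 3.77.

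**Figure D1:**
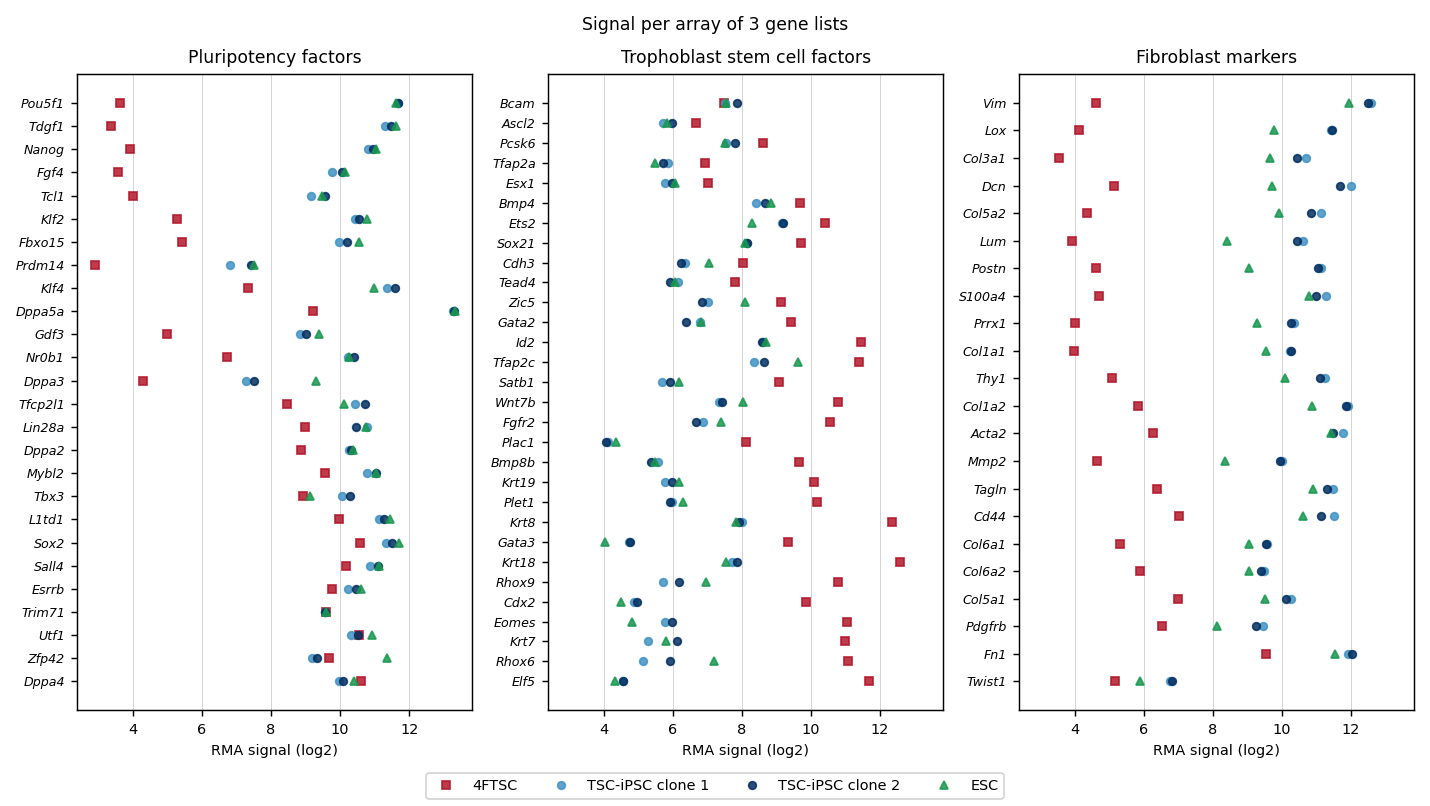
RMA signal (log2, x axis) on each array for the measured members (rows) of 3 lists, pluripotency factors, trophoblast stem cell factors and fibroblast markers, sorted by TSC-iPSC minus 4FTSC; squares are 4FTSC, circles the 2 TSC-iPSC clones and triangles ESC. For Elf5 the clones lie at 4.57 and 4.55 and 4FTSC at 11.67, whereas for Vim the clones lie at 12.58 and 12.49, ESC at 11.94 and 4FTSC at 4.63.

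Fibroblast markers gave the largest median of the 20 lists, 6.07 over 22 measured genes, with all 22 at least 2-fold higher in both clones and 21 called higher (22 when adjusted over the list alone). Vim, an intermediate filament gene of mesenchymal cells, rose 240-fold, and Col1a1, a fibrillar collagen chain, 76.3-fold. Dcn, Lum and Postn, matrix genes of fibroblasts, rose 103-fold, 95.9-fold and 88.4-fold. Of the 12 genes with the largest called rises, Vim and Lox belonged to this list and Cdh11 to the mesenchymal list, and Mmp13, Mmp3, Cxcl5, Il6 and Serpinf1 encode matrix proteases or secreted proteins. Mmp13 had the largest fold, 817, from 2.17 in 4FTSC to 11.85 and 11.84 in the clones; its 4FTSC value lay under the dim limit of 5.31, so that the fold and its rank depend on the background correction. The remaining genes were Pou5f1, Tdgf1, Armcx2 and Zfp979. The ESC array shared the elevation over 4FTSC, with 21 of the 22 fibroblast markers at least 2-fold higher, and TSC-iPSC lay above ESC by a median of 0.90. Genes with a mesenchymal role had a median of 3.37 over 11 genes, of which 8 rose and none fell (8 when adjusted over the list alone); 4 of the list's members, Vim, Fn1, Twist1 and Mmp2, were also fibroblast markers. Epithelial genes had a median of -1.72 over 18 genes, of which 6 fell, 11 when adjusted over the list alone, and none rose; 4 of them are keratins also counted among the trophoblast stem cell factors. The claudin gene Cldn3 fell 17.8-fold, whereas Cdh1, the epithelial cadherin, read 11.87 in 4FTSC and 10.72 and 10.96 in the clones and was not called.

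Signalling lists differed in the same comparison, on arrays that differed in fibroblast markers by a median of 6.07. These lists overlap with others, so some genes are counted again. LIF and Stat3 targets shared 2 genes with the pluripotency factors, and the Nodal and Lefty list shared 1, Tdgf1. FGF and MAPK targets shared 1 gene with LIF and Stat3 targets and 1, Ccnd1, with the cell cycle list. Targets of LIF and Stat3 had a median of 1.37 over 12 genes, of which 5 rose and none fell (8 when adjusted over the list alone). These included Socs3, the feedback inhibitor of the pathway, 2.61-fold, and Il6st, the shared receptor subunit, 2.42-fold. FGF and MAPK targets had a median of 1.01 over 15 genes, of which 4 rose and none fell (8 when adjusted over the list alone). They were Ccnd1 (8.06-fold), Fos (3.91-fold), Ier3 (3.76-fold) and Etv4 (2.01-fold). The Nodal and Lefty list had a median of 1.39 over 8 genes. There only Tdgf1 was called, against 4 genes when adjusted over the list alone, and Lefty2 read 3.47 in 4FTSC and 8.90 and 9.45 in the clones. In the cell cycle list, with a median of 0.11 over 18 genes, the D-type cyclin genes Ccnd1 and Ccnd2 rose (3 genes rose when adjusted over the list alone) and Cdkn1c, an imprinted cell cycle inhibitor, fell 16.1-fold (1 gene fell when adjusted over the list alone).

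Imprinted genes went both ways, with a median of -0.05 over 32 genes, of which 5 rose and 4 fell (8 and 6 when adjusted over the list alone). Those that fell were Igf2, a placental growth factor gene (12.9-fold), Cdkn1c, Phlda2 and Mest, and those that rose were Plagl1, Ndn, Impact, Cd81 and Dcn, of which Dcn is also a fibroblast marker. The maternally expressed transcripts of the Dlk1-Dio3 domain had a median of 3.04 over 3 genes. None was called over all genes and all 3 were when adjusted over the list alone; Meg3 read 6.88 in 4FTSC, 10.39 and 10.00 in the clones and 10.27 in ESC. Among genes of the DNA methylation machinery, with a median of 0.48 over 13 genes, 3 rose and none fell (5 and 1 when adjusted over the list alone). They were Dnmt3l, the cofactor of the de novo methyltransferases (10.6-fold), the dioxygenase gene Tet1 (7.35-fold) and Dnmt3a (2.42-fold). Dnmt3b, the other de novo methyltransferase, read 11.71 in 4FTSC and 10.44 and 10.34 in the clones. Chromatin factors had a median of 0.50 over 12 genes, of which 3 rose (Phc1, Kdm4c and Eed) and none fell (5 when adjusted over the list alone). Germline genes had a median of 0.54 over 20 genes, of which 3 rose (Hormad1, Mael and Rnf17) and 1 fell, Tex19.1 (7 and 2 when adjusted over the list alone). In the X inactivation list, with a median of -1.32 over 4 genes, Xist and Ftx fell and none rose (2 when adjusted over the list alone), and in the Y-linked list, with a median of 1.01 over 4 genes, Uty rose and none fell (2 when adjusted over the list alone), in the comparison whose libraries did not match for these genes.

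Lists of other lineages moved little as groups. Extraembryonic endoderm markers had a median of -0.12 over 21 genes. The basement membrane collagen genes Col4a1 and Col4a2 fell, and Pdgfra, Thbd and Plat rose (4 rose and 2 fell when adjusted over the list alone); these 3 were also at least 2-fold higher in both clones than in ESC, as 7 of the fibroblast markers were. Embryonic lineage markers had a median of -0.10 over 19 genes, with Eomes alone called (1 rose and 1 fell when adjusted over the list alone), and Otx2 read 2.21 in 4FTSC and 7.88 and 8.34 in the clones. Eomes is also counted among the trophoblast stem cell factors. The 2-cell-like markers, genes of the early embryo, had a median of -0.11 over 7 genes, with no member called by either adjustment.

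**Figure D2:**
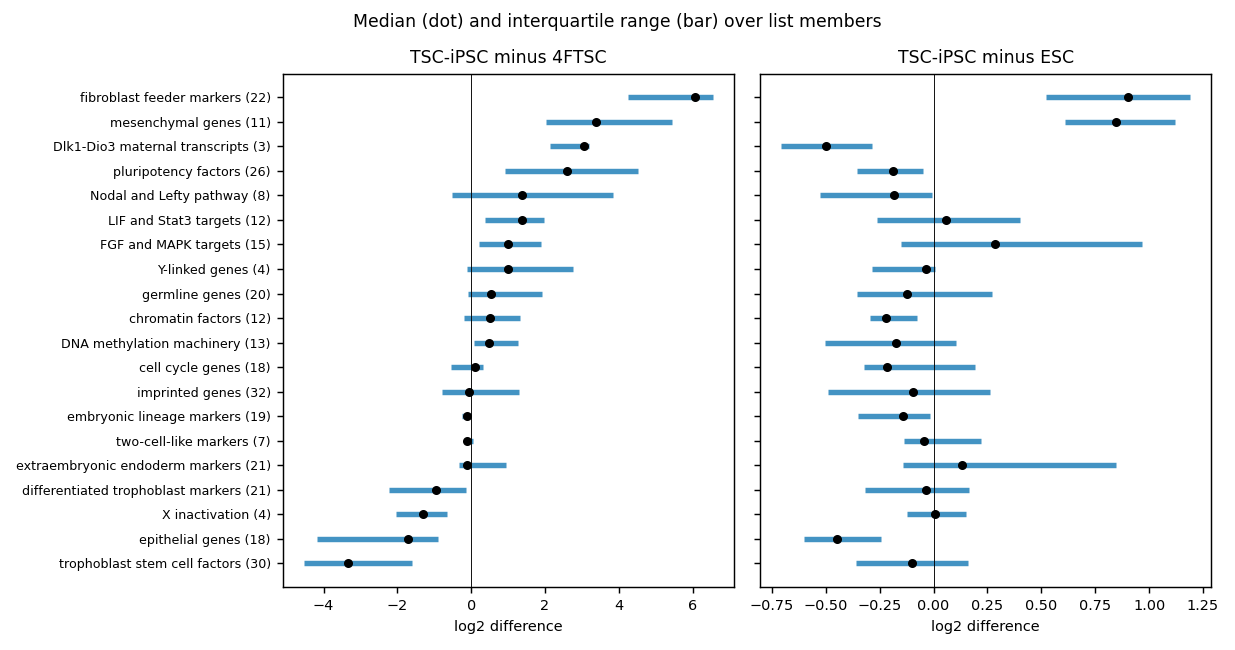
Median (dot) and interquartile range (bar) of the log2 difference over the members of each of 20 gene lists (rows, with the number of measured genes in brackets), for TSC-iPSC minus 4FTSC on the left and TSC-iPSC minus ESC on the right, with different x axes. Medians ran from -3.33 to 6.07 against 4FTSC, and lay under 1 in size for every list against ESC.

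These calls rest on a fit with 1 residual degree of freedom, in which the lone 4FTSC and ESC arrays were assumed to vary like the 2 clones, and with 1867 genes identical in both clones the adjusted p against 4FTSC went no lower than 0.0404. A fit without these genes, chosen after seeing the data, called 2596 genes (1640 rose and 956 fell), of which 1278 were among the 1321. Limma called 0 with treat (1752 genes at an unadjusted p under 0.05, against 7424 in the main fit), 0 of the probe sets (14310 at an unadjusted p under 0.05), and, in a 2-group fit of 4FTSC against the pluripotent arrays, 993 with all 3 of these (549 higher and 444 lower, 5500 at an unadjusted p under 0.05) and 0 without clone 1 or without clone 2 (3637 and 3264).

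Against ESC, the medians of the trophoblast and pluripotency lists lay between -0.19 and -0.04 in the main analysis, and fibroblast genes were higher. In both clones 447 genes were at least 2-fold higher than in ESC and 67 at least 2-fold lower; at least 4-fold, the counts were 26 and 6. Pluripotency factors lay at a median of -0.19, with 5 of 26 above ESC (percentile 0.52 of random lists; -0.08 without clone 1, -0.31 without clone 2 and -0.25 with the most variable probe set), and with Nanog at 10.80 and 10.97 in the clones and 11.03 in ESC. Those at least 2-fold lower in both clones were Zfp42, a marker of undifferentiated ESC, at 9.18 and 9.33 in the clones and 11.35 in ESC, and Dppa3, a gene of germ cells and naive pluripotency, at 7.28 and 7.52 against 9.31. Tbx3 was furthest above ESC, at 10.06 and 10.28 against 9.13. Trophoblast stem cell factors lay at a median of -0.10 (percentile 5.29; -0.26 with the most variable probe set). Rhox6 and Zic5 were at least 2-fold lower in both clones, at 5.13 and 5.92 against 7.21 and at 7.01 and 6.85 against 8.08, and none was at least 2-fold higher in both. Cdx2 read 4.89 and 4.97 in the clones and 4.51 in ESC, whereas Eomes read 5.78 and 5.98 against 4.83. Fibroblast markers lay at a median of 0.90, ranging from 0.19 to 2.12, all 22 above ESC, and mesenchymal genes at 0.85, both above all random lists.

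The other lists had medians of 0.50 or less in size against ESC, with -0.04 for differentiated trophoblast markers, -0.09 for imprinted genes, -0.50 for the Dlk1-Dio3 transcripts, 0.01 for X inactivation, -0.03 for Y-linked genes, 0.13 for extraembryonic endoderm and -0.14 for embryonic lineage markers. They were -0.18 for Nodal and Lefty, 0.06 for LIF and Stat3, 0.28 for FGF and MAPK, -0.18 for DNA methylation, -0.12 for germline, -0.04 for 2-cell-like, -0.45 for epithelial, -0.22 for chromatin and -0.22 for cell cycle genes. Against random lists, the lowest percentiles were 0.00 for epithelial genes (3 of 18 above ESC), 0.54 for cell cycle, 0.70 for Dlk1-Dio3, 1.59 for chromatin, 2.28 for embryonic lineage and 3.72 for DNA methylation genes, and the highest 99.5 for FGF and MAPK and 98.8 for extraembryonic endoderm. These ranks rest on the single ESC array. Fibroblast and mesenchymal genes lay above ESC on the same clone arrays. Whether a larger feeder share there lowers the other lists, pluripotency factors included, was not tested. Limma called 0 genes against ESC at an adjusted p under 0.05 (lowest 0.108), with 5171 genes at an unadjusted p under 0.05, and 610 (532 higher and 78 lower) in the fit without tied genes. Adjusted over each list alone, 9 fibroblast markers, 3 mesenchymal genes, 5 extraembryonic endoderm markers, 3 FGF and MAPK targets, 2 cell cycle genes and 1 imprinted gene were higher, and 1 imprinted gene, 1 extraembryonic endoderm marker and 1 DNA methylation gene were lower. Since the rule for named genes gave none here, the genes furthest from ESC were taken by size after their values were seen. Saa3 and Lcn2, acute-phase genes, were 15.9-fold and 14.8-fold higher in TSC-iPSC, and Dpys, a pyrimidine catabolism enzyme gene, 16.6-fold lower.

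The 4FTSC and ESC arrays, a comparison of 1 array with 1 array that was made by size and not tested, differed by at least 2-fold for 2594 genes, 1178 higher and 1416 lower in 4FTSC. The 8 genes furthest above ESC in 4FTSC were Elf5, Eomes, Morc4, Cited1, Septin4, Nat8l, 3830417A13Rik and Cdx2, with Elf5 160-fold higher. The 8 furthest below were Tdgf1, Pou5f1, Cxcl5, Cdh11, Armcx2, Mmp13, Zfp979 and Vim, with Tdgf1 299-fold lower. Trophoblast stem cell factors lay 2.82 above ESC in the median, pluripotency factors at -2.65 and fibroblast markers at -4.55.

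To place TSC-iPSC between the 2 references, each of the 2594 genes was put on a scale from 0, the 4FTSC value, to 1, the ESC value. The median position was 0.947 for clone 1 and 0.949 for clone 2. Of these genes, 2325 (89.6%) lay past the midpoint in the mean of the clones. The median was 1.04 for the 1416 genes higher in ESC and 0.864 for the 1178 genes higher in 4FTSC, and the 21 fibroblast markers in the set had a median of 1.20. Genes higher in both clones than in 4FTSC included 1152 that were also higher in ESC, against 121.3 expected for independent lists, and the lower genes shared 747 against 57.0 expected. Across genes, which are not independent replicates, the 2 differences from 4FTSC had a Pearson r of 0.917 against a simulated 0.577 for a shared 4FTSC array with no effect, and a covariance of 0.863 against 0.0181. The controls could not be split with 1 array, so part of the excess may come from the shared 4FTSC array.

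**Figure D3:**
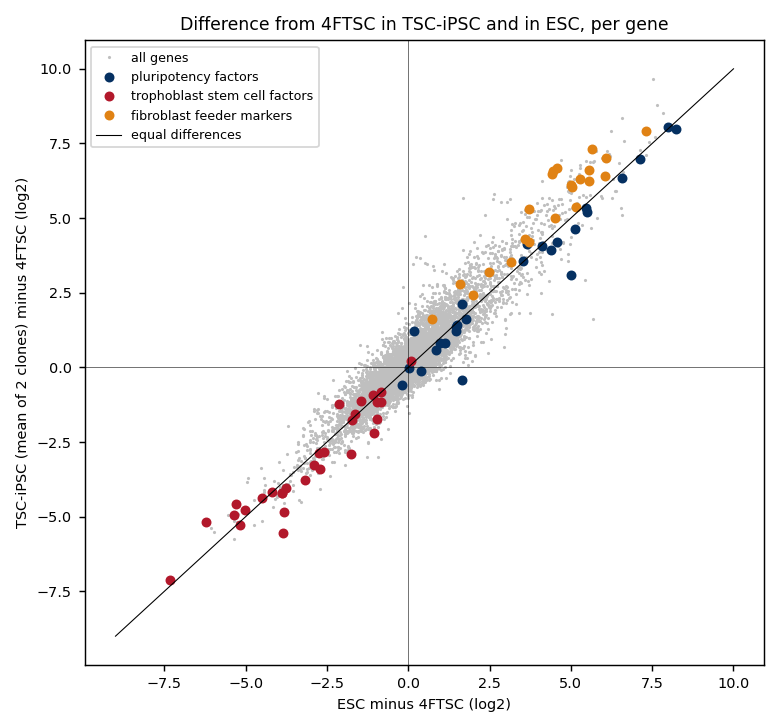
Log2 difference from 4FTSC for each gene (points) in ESC (x axis) and in TSC-iPSC, mean of 2 clones (y axis), with members of 3 lists in colour and a line of equal differences. The Pearson r was 0.917; the fibroblast markers lie above the line, as all 22 were higher in TSC-iPSC than in ESC.

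By whole profiles, too, the clones were closer to ESC than to 4FTSC. Across the 18194 genes, Pearson's r was 0.997 between the clones, 0.984 and 0.986 between the clones and ESC, and 0.909 and 0.912 between the clones and 4FTSC. The 4FTSC and ESC arrays correlated at 0.923, so by this measure the clones lay further from 4FTSC than ESC did. Fibroblast genes, far higher on the clone and ESC arrays than on 4FTSC, count towards these values and towards the positions above. The clones and ESC were also both grown in ESC medium with Lif, unlike 4FTSC. How much either contributes was not tested. All 6 pairs of arrays were compared, with no p-value, since genes are not replicates.

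The clones differed from each other by at least 2-fold for 23 genes, 16 higher in clone 1 and 7 in clone 2, with a median SD between clones of 0.065 over all genes. Sema5a, a guidance receptor ligand, read 6.39 in clone 1 and 4.38 in clone 2, and the nuclear RNA Malat1 11.08 and 9.28. Plau, Cybb, Ubn1, Crim1, Taf15 and Dhx36 were the next highest in clone 1, and the 7 higher in clone 2 were B4galnt2, Col26a1, Krtap16-3, Plscr2, 6330415B21Rik, Irf4 and Trim66. Krtap16-3, Plscr2, 6330415B21Rik, Irf4 and Trim66 lay under the dim limit of 5.31 on every array, so their differences depend on the background correction. A2m came next, at 5.80 and 6.80, just under 2-fold. The count depends on how a gene is represented, with 107 genes when its most variable probe set was taken and 9 when its probe sets were averaged. Without dim genes it was 18.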

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

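The comparisons of named genes leave out the 932 probe sets that carry several gene symbols and the 9211 that carry none. Among 10092 of these, 62 were at least 8-fold higher in both TSC-iPSC clones than in 4FTSC and 18 at least 8-fold lower, which is a signal that no comparison of named genes used, although the probe-set-level fit included these probe sets. At 2-fold the counts were 253 and 174. No explanation was tested for them, and no group had the 4 samples needed to look for a sample far from the others.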

How the results depend on the processing

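Leaving out tied genes, leaving out genes at least 0.5 above ESC, and 1 variance for all genes were chosen after seeing the data. Genes called against 4FTSC numbered 2024 without dim genes, 2335 after quantile normalisation, 2625 after median centring, 839 with robust eBayes, 2488 with no minimum difference, 678 at a log2 difference of at least 2, 2596 without tied genes, 798 without genes at least 0.5 above ESC and 2640 with 1 variance; they numbered 0 with limma treat, 0 at probe set level and, against 993 (549 higher) in the 2-group fit of all arrays, 0 to 1321 when 1 array was left out (0 without either TSC-iPSC clone in that fit, 1321 without ESC, which leaves only the clones against 4FTSC). Against ESC, calls numbered 621 after median centring, 610 without tied genes and 637 with 1 variance. Limma's prior degrees of freedom (main 0.61) were 0.73 without dim genes, 1.27 after quantile normalisation, 2.98 after median centring, 0.39 with robust eBayes and 6.64 without tied genes. In the last of these, leaving out tied genes was the only change. Median centring shifts the clones by different amounts (log2 medians 5.323 and 5.306), so it also unties genes. Beyond this, the cause of the changes was not tested. Fewer genes met stricter size limits by construction: at log2 2, 941 in both clones against 4FTSC (1560 at log2 1 without genes at least 0.5 above ESC), 32 against ESC, 874 between 4FTSC and ESC and 1 between clones, where the mean of probe sets gave 9 and the most variable 107. The median position (main 0.952) was 0.963 with mean probe sets, 0.949 with the most variable, 0.958 without dim genes, 0.950 after quantile normalisation, 0.942 after median centring, 1.01 at 4-fold, 0.970 as a mean, and 0.947 to 0.949 with a single clone. The correlation with 4FTSC (main 0.911) was 0.887 with the most variable probe set, 0.789 without dim genes and -0.0934 over the 1000 most variable genes, and with ESC (main 0.985) 0.980, 0.965 and 0.886; the cause was not tested. No called value reversed its direction. Of list medians 188 stayed within the spread between the clones and 92 moved by more, and of named genes 175 and 28. Against 4FTSC, with mean probe sets the median of fibroblast markers moved from 6.07 to 4.46, Dlk1-Dio3 from 3.04 to 1.74, LIF and Stat3 from 1.37 to 0.88, FGF and MAPK from 1.01 to 0.70 and cell cycle from 0.11 to -0.03 (-0.12 with the most variable). Y-linked genes moved from 1.01 to 3.24 with the most variable probe set and 3.39 without dim genes, where Nodal and Lefty moved from 1.39 to 2.71 and germline from 0.54 to 1.25. Against ESC, with mean probe sets LIF and Stat3 (0.06) moved to -0.02, X inactivation (0.01) to -0.09 and DNA methylation (-0.18) to -0.41 (-0.48 with the most variable, where germline went from -0.12 to 0.00, embryonic lineage from -0.14 to -0.29, and pluripotency and trophoblast stem cell factors from -0.19 and -0.10 to -0.25 and -0.26). Without dim genes 2-cell-like (-0.04) moved to 0.17 and Y-linked (-0.03) to -0.46. Without clone 1 or clone 2, pluripotency was -0.08 or -0.31 and extraembryonic endoderm (0.13) 0.31 or 0.00. No paired analysis was possible because the groups share only 1 replicate number. The number of arrays limits the precision, and dim signals near background limit folds.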

Other observations

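Some genes were picked by hand after their values were seen, with no test of whether any class of genes was over-represented. Saa3 read 11.58 and 11.23 in the clones against 7.42 in ESC and 5.73 in 4FTSC, and Lcn2 8.71 and 8.68 against 4.80 and 4.30. The neutrophil gene S100a8 read 7.52 and 7.65 against 4.28 in ESC, the lysozyme gene Lyz1 9.29 and 8.97 against 5.94, the chemokine genes Ccl6 7.40 and 7.22 against 3.99 and Ccl8 9.97 and 9.81 against 7.20, and the scavenger receptor gene Olr1 7.66 and 7.45 against 4.73. Cd14, a co-receptor for bacterial lipopolysaccharide, read 7.03 and 6.81 against 5.58, whereas the pan-leukocyte gene Ptprc read 2.98 and 2.99 against 2.81. The opioid precursor gene Penk and Igfbp5 were 8.22-fold and 6.60-fold above ESC, and both read under 5 in 4FTSC, at 4.63 and 3.95.

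Among genes lower in both clones than in ESC, the following were picked in the same way. Ina, a neuronal intermediate filament gene, read 7.11 and 6.97 in the clones against 9.52 in ESC, Neurod1 4.98 and 5.04 against 6.92, and Tubb3 6.83 and 7.10 against 8.30. Ptch1 read 8.73 and 8.90 against 10.24 and Gli1 6.64 and 6.70 against 8.01. In 4FTSC these 5 genes read 4.10, 3.18, 5.16, 8.50 and 5.05, below ESC for each.

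Tests chosen only after the result was seen were those of scaling, of transcription by the pluripotent cells, of male feeder cells and of an ESC array that stands apart; the others were set before their values were seen. Fibroblast genes were far higher on the TSC-iPSC and ESC arrays than on 4FTSC. The list's median stayed at 6.01 or more under quantile normalisation and median centring. The deposited values were already quantile normalised, with array medians between 38.6 and 40.2, so these steps could hardly move a list's median. This test therefore decides nothing about scaling between arrays. Feeder fibroblasts in the cultures may account for the higher fibroblast genes. The 20 further fibroblast genes, with Fbln2 at 11.31 and Igfbp7 at 11.25 in clone 1, were 2.41 higher in ESC than in 4FTSC in the median. The 15 markers of other tissues stood at 0.00. For the trunk Hox genes, at least 0.5 had been set as the prediction on ESC and both clones. However, they stood at -0.0624 in ESC and at -0.14 and 0.00 in the clones, so the prediction was not met. They were 0.39 higher in TSC-iPSC than in ESC (11 of 15 genes above 0, percentile 99.98 of random lists). Against 4FTSC the Hox members went both ways, with 7 of 15 above 0 in TSC-iPSC, so that these medians decide nothing. For example, Hoxc8 read 4.88 in 4FTSC, 7.68 and 7.41 in the clones and 6.00 in ESC, and Hoxc9 7.40, 6.73, 6.73 and 6.73. Transcription of these genes by the pluripotent cells themselves stays open, although the fibroblast and pluripotency lists lay 1.09 apart between TSC-iPSC and ESC, since lines can differ in single programmes and no array of feeder cells alone was analysed here.

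Y-linked transcripts were seen on the TSC-iPSC and ESC arrays and not on the 4FTSC array, where Xist was high. Male feeder cells as the only source on the TSC-iPSC and ESC arrays alike would place these transcripts above ESC in TSC-iPSC, like the fibroblast markers. Of the probe sets above the dim limit, Eif2s3y stood at -0.95, Uty at 0.0348 and a second probe set of Uty at -0.29 (TSC-iPSC minus ESC). Each lay below the lowest fibroblast marker (0.19). A dim probe set of Kdm5d went the other way, at 4.12 and 4.36 in the clones and 3.11 in ESC. However, 18 of the 20 further fibroblast genes lay above 0, so some fibroblast genes lay lower than the first probe set of Uty. The bound from the first list therefore cannot exclude this source. Male feeders may also bring the Y-linked transcripts to TSC-iPSC alone, if the ESC have a Y chromosome of their own. Clone 2 minus clone 1 was 0.62 for Eif2s3y and 0.17 for the second probe set of Uty. Both lay above the interquartile range of -0.25 to -0.06 for fibroblast markers. The first probe set of Uty stood at -0.15, and with the probe sets of Uty disagreeing this stays open. TSC-iPSC cells that carry a Y chromosome, so that the 4FTSC array would be of cells of another sex, would have 1 active X: X-linked genes relative to autosomal ones lay 0.044 and 0.023 above 4FTSC and 0.018 and 0.023 above ESC, in line with this. Cells with 2 X chromosomes that lost 1 of them would give these values too, and over 176 X-linked genes of a mean log2 signal of at least 8, a limit chosen after seeing the data, the values were 0.065, 0.027, -0.03 and 0.00. Whether an array is mislabelled, feeders were male or the parental line was of mixed sex was not resolved, and every comparison with 4FTSC rests on its label.

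For genes at least 2-fold apart between TSC-iPSC and ESC in both clones, 3 explanations were set side by side. A larger feeder share on the TSC-iPSC arrays would make the genes above ESC follow those higher in ESC than in 4FTSC, which held for 40.0% of the 447 genes, above the 95th percentile of random lists (13.4%) but short of the 50% set in advance, so it may account for a part and stays open. The 447 genes were chosen as lower in ESC than in the clones, which tends to lower this share. Expression kept from the parental 4FTSC had been predicted to take the share above the 95th percentile of random lists in both directions, which it did. Of the higher genes, 18.8% lay at least 2-fold higher in 4FTSC than in ESC (95th percentile 11.2%). Of the 67 lower genes, 76.1% lay at least 2-fold lower (17.9%), among them Zfp42, at 9.68 in 4FTSC. These shares also count genes far from 4FTSC in the clones, such as Ifitm1 (34.2-fold higher) and Dppa3 (8.52-fold higher). They therefore do not show that expression was kept. Both shares use the same ESC array, which inflates them, and of the 135 genes on the 4FTSC side of ESC, 90 (66.7%) had TSC-iPSC within 2-fold of 4FTSC, as would also be seen if the single ESC array alone stood apart. A further ESC array would be needed to separate kept expression from an ESC array that stands apart. It would not settle the feeder share.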
